A study of Saccharomyces cerevisiae with 25 samples.

How the data were processed

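RNA was sequenced in 25 samples of the budding yeast Saccharomyces cerevisiae. The strain background was BY4741, a laboratory haploid of mating type a, and the strain carried a yellow fluorescent protein gene behind the PHO84 promoter together with a DAmP allele of PHM3. PHM3 is an older name of VTC4, the catalytic subunit of the complex that makes polyphosphate in the vacuole membrane. A DAmP allele (decreased abundance by mRNA perturbation) disturbs the 3′ end of the transcript, which usually lowers its amount. Per the labels, cells were grown in medium rich in phosphate, washed and moved to medium without phosphate, and were then sampled at intervals of 15 min for 6 hours. One sample was taken in high phosphate at 0 min and 24 in no-phosphate medium from 15 to 360 min. Total RNA was extracted with a 96-well kit after lyticase treatment, and cDNA was sequenced on an Illumina HiSeq 2500, per the labels' protocols.

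The reads were aligned with Bowtie against genome build R64, per the submitters' processing notes. The mapping settings, the counter, the annotation and whether counting used the strand were not given in the sources used here. The authors deposited one table of log2 values, with 1 column per sample. Raised to the power of 2, each column sums to 1000000, so the deposited values are log2 RPM (reads per 1000000 reads). The series' design text describes values set relative to the first time point, which the deposited log2 values do not show, and they were used as log2 RPM. Low values in each column are whole multiples of 1 step, and the lowest value equals 10 steps in every column. The table therefore lists a gene only from 10 reads upwards, and a missing value stands for fewer. Dividing by the step gave the reads behind each column: of the values under 200 reads, 94.9 to 97.5% per library came out within 0.02 of a whole number, and of all values 92.1 to 95.3%. The tolerance was set after the values had been seen. Genes with many fractional values include ones with a near-identical copy, such as PHO5, PHO11 and PHO12 and ribosomal protein pairs, so reads of such copies appear to have been divided between them. In 616 of the 6701 rows fewer than 95% of the values were whole.

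Recovered depth was 4.275 M reads at 0 min and ranged over the no-phosphate libraries from 4.263 M at 120 min to 0.147 M at 345 min, with a median of 1.12 M over the 25 libraries. The libraries at 270 min (0.377 M), 330 min (0.459 M) and 345 min were the 3 under 0.5 M reads. Correlation of consecutive samples across genes was between 0.874 and 0.987. These genes are not independent replicates. Intervals from read numbers cover counting error only, since reads amplified by PCR are not independent molecules.

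Of the 6701 rows, 51 had no gene name and 0% of the reads, and 2 shared the name IMP2. These were left out, which left 6648 names. Matched against the RefSeq annotation of R64, 5915 names were found directly, 47 as a synonym and 686 not at all. Coordinates are those of this annotation, counted from 1. Of the annotated genes used, 96.7% had a length that is a multiple of 3, so lengths are coding lengths. A total of 920 rows held no value in any sample, and 2955 held a value in all 25. Genes were tested when they had a value at 0 min and in at least 4 of the 6 samples of each window, which 4742 did. This filter was chosen after the missing values had been counted and before any test was run.

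The 24 no-phosphate samples were divided by time into 4 windows of 6 samples (15 to 90, 105 to 180, 195 to 270 and 285 to 360 min), and the 0 min sample stood alone. The samples of a window are consecutive time points. Nothing in the labels says that they came from separate cultures, so the p-values measure the scatter between consecutive samples, which includes real change within a window. A model of group means was fitted to the log2 values of all 25 samples with limma 3.58.1 in R 4.3.3, with moderated contrasts between windows and against 0 min. The single 0 min library was assumed to vary like the others, and any error in it enters both comparisons against it. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. Variation along the course was tested in limma with a moderated F-test on a natural cubic spline of time with 4 degrees of freedom over the no-phosphate samples, with the same adjusted p and a fitted range of at least 1. The median residual standard deviation was 0.329 in the window model and 0.300 around the spline.

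Of 32 gene lists written down beforehand, 28 had at least 3 tested members. They were tested with limma's camera procedure on the moderated statistics, with its preset correlation of 0.01 between genes and again with a correlation estimated from the residuals. The version that works from the statistics was used because of the missing values. The residuals of the window model include real change within a window, which can raise the estimate when genes of a list change together. A call lost with an estimated correlation is therefore not evidence that the list did not change. The lists covered the PHO regulon, phosphate signalling, ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, the general stress response, trehalose and glycogen metabolism, glycolysis, hexose transporters, the TCA cycle, the respiratory chain, amino acid, sulfur and purine synthesis, the iron and zinc regulons, nitrogen catabolite genes, autophagy, the proteasome, chaperones, ergosterol and phospholipid synthesis, histones, G1/S, G2/M and M/G1 genes, the cell wall and the mating response. Mating type alpha genes and meiosis genes had 2 tested members each, and mitochondrially encoded RNAs and the auxotrophy markers of BY4741 had 0, so these 4 lists were not tested as lists. The time of induction of a PHO gene was the first time at which the running median of 3 consecutive samples reached 0.5 of its highest value above 0 min. This fraction was taken on the log2 scale, so it is not 0.5 of the highest RPM.

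The design, the alternatives, the lists and the naming rule were fixed before the data were examined. The rule named, for 285 to 360 min against 15 to 90 min and for each comparison against 0 min, up to 10 rises and 10 falls with the largest change among called genes with a standard symbol and a value in all 25 samples. It further named every measured PHO gene, VTC4 in every sample, and up to 4 called members of each other list.

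The limma contrasts, the spline and the term for 5 libraries used below were tested on simulated data for the 4742 genes, with 50 genes changed at each size. Gene lists, the lag-1 correlation and induction times were simulated separately. Unchanged genes were called as well: 2 for 285 to 360 against 15 to 90 min, 4 for 15 to 90 min against 0 min and 12 for 285 to 360 min against 0 min. For 285 to 360 against 15 to 90 min, 46% of genes changed by 1 on the log2 scale were recovered, 94% at 1.5 and 100% at 2 and 3. For 15 to 90 min against 0 min these shares were 16, 70, 90 and 100%, and for 285 to 360 min against 0 min 20, 70, 88 and 100%. Recovery at 1.5 was 96, 94 and 98% for the 3 pairs of adjacent windows in time order, and 72% for the spline. In 20 simulated data sets the list test called 0 unchanged lists, and it called the PHO regulon, raised by 1, in 20 of them. The noise in these sets was independent between genes and between samples. In the data the residuals of the window model, which include real change within a window, gave an estimated correlation of 0.663 within the PHO regulon. Their lag-1 correlation was 0.517. The 0 false calls therefore do not carry over to lists whose genes move together. Simulated induction times were recovered within 15 min in 100% of 200 genes for a step of 2 on the log2 scale, and likewise for a step of 4. Each simulated course held a single sharp step, so this share does not apply to genes that rose, returned in part and rose again.

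Alternatives covered each sample centred on its median, quantile normalization, other filters on missing values, every second sample, a correlation of lag 1 between consecutive samples, no fold threshold, a robust spread with an intensity trend, other splines, other window sizes, leaving out each no-phosphate sample in turn and other definitions of the induction time. Precision weights from the recovered reads (limma's voom), filling missing values at 10 reads and leaving out sets of libraries were added later. Count models were not used because the deposited unit is log2, and alternatives for counts and for a pseudocount did not apply. Splits of the samples, at most 100 per comparison, were drawn with a fixed seed. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Strains without the DAmP allele were not analysed here. After the results were seen, rises were listed whose reference mean lay under the floor of every later library with a value.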

Results

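RNA from yeast cells carrying a DAmP allele of VTC4 was sequenced during 6 hours without phosphate. One library was made from cells in high phosphate at 0 min, and 24 libraries followed at intervals of 15 min after the move to no-phosphate medium. These 24 were compared as 4 windows of 6 consecutive time points, so n = 6 per window and n = 1 at 0 min. Recovered depth fell from 4.275 M reads at 0 min to a range of 0.147 to 0.781 M in the 6 libraries from 285 to 360 min. Values are log2 RPM (reads per 1000000 reads), differences are log2 with their standard error (SE), and window means carry the standard deviation (SD). The median log2 difference of all 4742 tested genes was not 0: it was 0.10 for 15 to 90 min against 0 min, 0.47 for 285 to 360 min against 0 min and 0.36 for 285 to 360 against 15 to 90 min. The term "relative" below marks a difference from which this median was subtracted.

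VTC4, the catalytic subunit of the vacuolar polyphosphate polymerase and the gene with the DAmP allele (chromosome X, 411234 to 413399, minus strand), was detected in every sample. Its level was 6.40 log2 RPM at 0 min. From 15 to 90 min it was 6.71, 7.0, 6.95, 6.84, 6.35 and 7.36, and from 105 to 180 min 6.64, 5.87, 7.11, 7.15, 7.28 and 7.41. From 195 to 270 min it was 7.73, 7.81, 7.60, 7.75, 7.53 and 8.03. From 285 to 360 min it was 7.73, 7.73, 8.06, 8.04, 10.36 and 7.51, the value of 10.36 being that of the shallowest library, at 345 min. A library without the allele was not analysed here, so whether the allele lowered VTC4 could not be checked.

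The comparison of the first 90 min with 0 min asks what changed soon after phosphate was withdrawn. Of the 6 genes called as higher, 5 belong to the PHO regulon and serve phosphate uptake, polyphosphate synthesis or phosphate signalling. SPL2, a regulator of low-affinity phosphate transport (VIII, 374654 to 375100, minus strand), rose 6.81-fold (log2 2.77 ± 0.45 SE, limma adjusted p = 0.00191). VTC3, a subunit of the polyphosphate polymerase complex (XVI, 514511 to 517018, minus strand), rose 4.89-fold (2.29 ± 0.26, limma adjusted p = 8.31e-06). PHO84, the high-affinity phosphate transporter (XIII, 24037 to 25800, minus strand), rose 4.51-fold (2.17 ± 0.30, limma adjusted p = 0.000198). Its gene overlaps the annotated non-coding RNA gene YNCM0001W, so some of its reads are uncertain without known strand counting.

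VTC1, another subunit of that complex (V, 302806 to 303195, plus strand), rose by 1.83 ± 0.38, and PHO81, the inhibitor of the Pho80-Pho85 kinase (VII, 954674 to 958210, minus strand), by 1.5 ± 0.27 (limma adjusted p = 0.0361 and 0.00976). The call of VTC1 was lost in 13 of 39 alternative settings, with limma adjusted p up to 0.840. For each of these 5 genes all 6 samples lay above the 0 min value. The genes were chosen by their calls in this comparison, so this describes the calls and adds no separate support. Of the 19 tested genes of the PHO regulon, the targets of the transcription factor Pho4, these 5 were called over all genes and 11 when adjusted over the list alone. The regulon stood higher than other genes (relative median 1.24, limma's camera test, adjusted p = 2.33e-35), and this call held with an estimated correlation (adjusted p = 0.00314). Members that did not pass included the secreted acid phosphatases PHO12 (2.01, limma adjusted p = 0.151) and PHO5 (1.29, limma adjusted p = 0.920), and VTC4 itself (0.47, limma adjusted p = 0.953).

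Other lists stood apart in the same window by less per gene, with 0 members called over all genes. General stress response genes (relative median 0.97) and trehalose and glycogen genes (0.83) stood higher in limma's camera test, with adjusted p of 1.24e-15 and 2.86e-05. Heat shock chaperones (0.53, adjusted p = 5.06e-05) and the TCA and glyoxylate cycle (0.36, adjusted p = 1.49e-05, 2 members called when adjusted over the list alone) did so too. Ribosome biogenesis genes stood lower (relative median −0.77, adjusted p = 3.81e-28), as did subunits of RNA polymerases I and III (−0.63, adjusted p = 8.90e-09) and ribosomal proteins (−0.47, adjusted p = 3.78e-10). With an estimated correlation these 7 calls were lost, with limma's camera adjusted p = 0.512 for each except the ribosomal proteins, where adjusted p = 0.681. Smaller differences passed limma's camera test for respiratory chain (relative median 0.23, adjusted p = 4.38e-05), glycolysis (0.26, adjusted p = 5.28e-05) and proteasome genes (0.19, adjusted p = 0.000478), and on the lower side for iron (−0.25, adjusted p = 0.0363), phospholipid (−0.24, adjusted p = 0.0496) and M/G1 genes (−0.19, adjusted p = 0.0496). These 6 were lost as well (limma's camera test with an estimated correlation, adjusted p = 0.681 for the proteasome, 0.594 for M/G1 and 0.512 for the others).

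In limma, 7 genes passed both thresholds in this comparison, 6 up and 1 down, and 210 had an unadjusted p under 0.05. The sixth riser was YNL134C (1.21 ± 0.25, limma adjusted p = 0.0361), named after its value was seen. The single fall was FCP1, a phosphatase of the RNA polymerase II tail (XIII, 820256 to 822454, plus strand), at 9.83 log2 RPM at 0 min and 6.81 ± 0.12 SD from 15 to 90 min (log2 −3.02 ± 0.29 SE, limma adjusted p = 4.38e-07). Only 20% of its values were whole reads, so its level is uncertain, and the single 0 min library decides the difference. The 0 min library has no replicate: with every second sample from 15 to 345 min 2 calls were left and SPL2, PHO84, VTC1 and PHO81 lost theirs, and with a lag-1 correlation 3 were left, without SPL2, VTC1 and PHO81. Quantile normalization left 4 calls, without VTC1 and PHO81, and voom weights gave 12, whereas 49 genes were called without the 105, 120 and 135 min libraries, which also enter the shared spread.

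**Figure D1:**
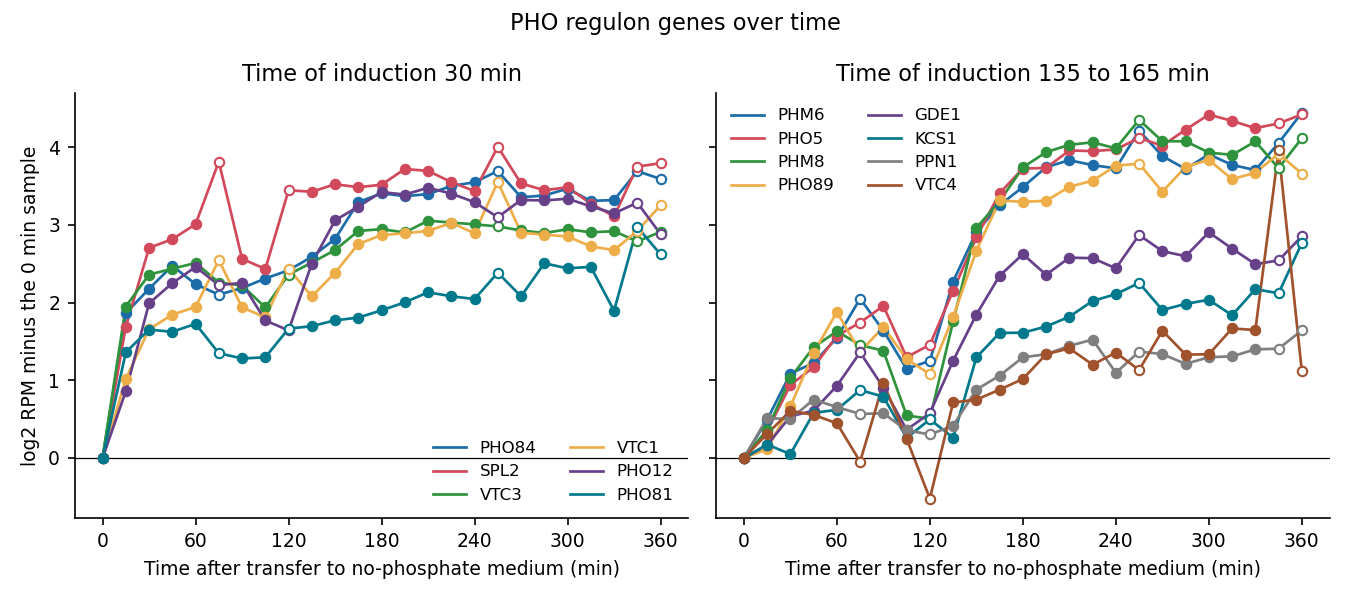
PHO regulon genes over the time course, as log2 RPM minus the 0 min sample (vertical axis) against minutes after the move to no-phosphate medium (horizontal axis), 1 point per library. The left panel holds genes with a time of induction of 30 min (PHO84, SPL2, VTC3, VTC1, PHO12 and PHO81) and the right panel genes with times of 135 to 165 min (PHM6, PHO5, PHM8, PHO89, GDE1, KCS1, PPN1 and VTC4). Open points mark the libraries at 75, 120, 255, 345 and 360 min, in which ADA2 was low, and VTC4 at 345 min stands far above its neighbours.

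From 15 to 90 min to 285 to 360 min, members of the stress, storage carbohydrate, nitrogen, autophagy and PHO lists rose, and nearly all ribosomal protein transcripts fell. The calls of the first 5 of these lists were lost with an estimated correlation (limma's camera test, adjusted p = 0.565, 0.698, 0.296, 0.406 and 0.406). PHO5, the main secreted acid phosphatase (II, 429548 to 430951, minus strand), went from 9.79 ± 0.59 to 12.83 ± 0.08 log2 RPM (SD, n = 6 each), an 8.22-fold rise (log2 3.04 ± 0.31 SE, relative 2.68, limma adjusted p = 7.60e-08). HSP26, a small heat shock protein (II, 382030 to 382674, plus strand), rose 21.7-fold, from 7.29 ± 0.46 to 11.73 ± 0.47. The ribosomal protein gene RPS22A (X, 74910 to 75302, minus strand) fell by 2.78 ± 0.40 SE (relative −3.14, limma adjusted p = 5.16e-06).

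Of the 19 tested PHO genes 13 rose and 0 fell, over all genes and when adjusted over the list alone. PHM8, a lysophosphatidic acid phosphatase, rose by 2.76 ± 0.39, PHM6 by 2.60 ± 0.32 and PHO89, a sodium-phosphate cotransporter, by 2.56 ± 0.32. GDE1, a glycerophosphodiesterase, rose by 1.93 ± 0.28, KCS1, an inositol hexakisphosphate kinase, by 1.64 ± 0.23, and PHO8, the vacuolar alkaline phosphatase, by 1.63 ± 0.30. Smaller rises were found for PHO11 (1.40), VTC4 (1.37 ± 0.33, limma adjusted p = 0.00149), PHO84 (1.29 ± 0.16, limma adjusted p = 1.11e-06), HOR2 (also known as GPP2), a glycerol phosphatase (1.24), PHO12 (1.20) and VTC1 (1.06). When each sample was centred on its median, PHO84 (0.88), VTC4 (0.96), PHO12 (0.79), HOR2 (0.83), VTC1 (0.65) and PHO11 (1.00) lay under the fold threshold, which left 7 calls. VTC4 also lost its call without the 345 min library (0.95).

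PHO81 (0.98), PPN1, a polyphosphatase (0.78), VTC2 (0.75), SPL2 (0.71) and VTC3 (0.60) did not reach the fold threshold of 1, and PHO86, which is needed for the export of Pho84 from the endoplasmic reticulum, was at 0.28 (limma adjusted p = 0.0809), or −0.12 after centring. The acid phosphatase genes PHO5, PHO11 and PHO12 share reads, with 0% whole values, so their separate levels are uncertain. The regulon as a list stood higher than other genes (relative median 0.92, limma's camera test, adjusted p = 3.60e-07). That call was lost with an estimated correlation (adjusted p = 0.406). GIT1, PHM7 and CTF19 of this list had too few values to be tested. Of 13 phosphate signalling and low-affinity transport genes 1 rose, DDP1, a diphosphoinositol polyphosphate phosphatase (1.34 ± 0.21), and the list did not pass (relative median 0.38, limma's camera test, adjusted p = 0.995).

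General stress response genes rose in 44 of 56 cases, with 0 falls (relative median 1.09, limma's camera test, adjusted p = 2.45e-09). The list call was lost with an estimated correlation (adjusted p = 0.565), and 27 members were called after centring. HSP26 (4.44 ± 0.34, relative 4.08, limma adjusted p = 1.84e-09), the hydrophilins GRE1 (4.37 ± 0.39) and SIP18 (4.11 ± 0.35), and MOH1 (3.77 ± 0.31) had the highest values of the list. Other genes among the 10 largest rises, ranked over genes with a standard symbol and a value in all 25 samples, were HPF1, a cell wall mannoprotein (4.08), FMP16 (3.96), GND2, a 6-phosphogluconate dehydrogenase (3.76), DDR2 (3.38), PAI3, an inhibitor of proteinase A (3.25), GPG1 (3.24) and TDH1, a glyceraldehyde-3-phosphate dehydrogenase (3.18). HPF1 and TDH1 held 4 and 12% whole values, so part of their reads is shared with similar genes.

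Among trehalose and glycogen genes 9 of 17 rose, including GPH1, glycogen phosphorylase (2.71 ± 0.46), GLC3, the branching enzyme (2.50 ± 0.42), PIG2 (2.11 ± 0.25) and GDB1, the debranching enzyme (1.89 ± 0.47). The list call (relative median 0.73, limma's camera test, adjusted p = 0.0438) was lost with an estimated correlation (adjusted p = 0.698) and without the 5 libraries of low ADA2 described below (adjusted p = 0.0652). Of 21 glycolysis and fermentation genes 5 rose and 1 fell, the risers including TDH1, ENO1 (2.25), PYK2 (1.51) and GLK1, glucokinase (1.25, overlapping YCL042W, lost in 7 of 41 settings). This list (relative median 0.16, limma's camera test, adjusted p = 0.0354) was lost with an estimated correlation (adjusted p = 0.698) and after centring (adjusted p = 0.0737). Of 7 hexose transporters only HXT5 rose, 17.7-fold (4.15 ± 0.36, or 3.11 under quantile normalization), and the list did not pass (limma's camera test, adjusted p = 0.195).

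Nitrogen catabolite genes, which cells use to take up and break down poor nitrogen sources, rose in 17 of 23 cases (relative median 1.03, limma's camera test, adjusted p = 2.24e-07). GAP1, the general amino acid permease, rose 6.26-fold (2.65 ± 0.36), the permease AGP1 by 2.40 ± 0.22, the repressor DAL80 by 2.39 ± 0.30 and the urea permease DUR3 by 2.25 ± 0.23. Autophagy genes rose in 13 of 18 cases (relative median 0.96, limma's camera test, adjusted p = 0.000125), with ATG8, which coats the growing autophagosome, at 2.11 ± 0.36, ATG22 at 1.85, and the selective autophagy receptors ATG19 and ATG34 at 1.76 and 1.69. With an estimated correlation both list calls were lost (adjusted p = 0.296 and 0.406), and after centring 11 nitrogen and 7 autophagy genes were called.

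Genes of the respiratory chain and ATP synthase rose in 16 of 36 cases (relative median 0.62, limma's camera test, adjusted p = 5.85e-11). The call was lost with an estimated correlation (adjusted p = 0.232), and 2 members were called after centring. The inhibitors of the ATP synthase INH1 (1.74 ± 0.26) and STF1 (1.54 ± 0.29) and the complex III subunits QCR10 (1.38) and CYT1 (1.37) had the largest values. Of 25 TCA and glyoxylate genes 5 rose, among them the succinate dehydrogenase subunits SDH2 (1.46) and SDH4 (1.43), IDP2 (1.45) and ACH1 (1.3), and the list did not pass (limma's camera test, adjusted p = 0.0507).

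Ribosomal protein genes fell in 135 of 137 cases, with a median of −2.24 (relative −2.61, limma's camera test, adjusted p = 1.08e-136). Of the 15 lists called in this comparison, 9 up and 6 down, this was the single one that held with an estimated correlation (adjusted p = 0.00603). Among genes with a standard symbol and a value in all 25 samples, the 10 largest falls were in this family: after RPS22A came RPL31A (−2.65 ± 0.51, limma adjusted p = 0.000141), RPL27A (−2.64), RPS1B (−2.54), RPL9A (−2.53), RPS9B (−2.53), RPL24A (−2.52), RPS18B (−2.52), RPS17A (−2.52) and RPL34A (−2.51). RPL8A, lacking a value in 1 sample and so outside this ranking, fell by 2.65. Most of these share reads with a near-identical copy, the share of whole values being between 0 and 40% except for RPL31A at 84%, so a fall is better read for a pair than for one copy.

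Ribosome biogenesis genes differed far less between these windows: 1 of 85 fell, UTP22, a component of the small subunit processome (−1.19 ± 0.25), with a relative list median of −0.46 (limma's camera test, adjusted p = 5.61e-06). The first window was already low against 0 min (relative median −0.77), and 68 of the 85 genes varied along the course in the spline test. The small difference therefore does not mean that these genes stayed level. RNA polymerase I and III subunits had 0 of 20 called and a relative median of −0.50 (limma's camera test, adjusted p = 0.00281). These list calls were lost with an estimated correlation (adjusted p = 0.694 and 0.619), and UTP22 lost its call without the 5 libraries of low ADA2.

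M/G1 cell cycle genes rose in 10 of 22 cases (relative median 0.59, limma's camera test, adjusted p = 3.62e-05), among them PCL9, a cyclin of Pho85 (1.67), RME1, a repressor of meiosis (1.53), DSE4, a glucanase of daughter cells (1.48), and the G1 cyclin CLN3 (1.22), which lost its call in 7 of 41 alternative settings. After centring 3 of the M/G1 genes were called. G2/M genes had 1 of 16 called, the B-type cyclin CLB1 (1.49 ± 0.17), and a relative median of 0.43 (limma's camera test, adjusted p = 0.000390). G1/S genes had 0 of 23 called and a relative median of −0.28 (limma's camera test, adjusted p = 0.0438), and histones 0 of 10 (adjusted p = 0.857). With an estimated correlation the first 3 of these calls were lost (adjusted p = 0.232 for both M/G1 and G2/M and 0.6 for G1/S), and without the 5 libraries of low ADA2 the G1/S list had adjusted p = 0.314.

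Sulfur and methionine genes had 2 of 19 called, the S-adenosylmethionine synthetases SAM1 and SAM2, which fell by 1.81 ± 0.21 and 1.39 ± 0.28. The list tested lower than other genes (limma's camera test, adjusted p = 0.0166) with a mean of −0.05 and a median of 0.16 (relative −0.20), and lost its call with an estimated correlation (adjusted p = 0.565). Proteasome genes had 0 of 32 called and a relative median of −0.27 (limma's camera test, adjusted p = 0.0349, lost with an estimated correlation at adjusted p = 0.720, and under quantile normalization at adjusted p = 0.371).

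The remaining lists did not pass limma's camera test. Among 62 amino acid synthesis genes 8 rose (adjusted p = 0.398), including glutamine synthetase GLN1 (1.52), SER3 (1.37), LYS20 (1.28) and HIS4 (1.26), of which SER3, LYS20 and HIS4 lost their calls in 3, 5 and 1 of the alternative settings. Among 17 purine genes MTD1 (1.34) and ADE17 (1.22) rose and IMD2, an IMP dehydrogenase, fell by 1.25 (adjusted p = 0.905). In the iron regulon 1 of 17 rose, the reductase FRE6 (1.21, lost in 7 of 39 settings, adjusted p = 0.449 for the list), and in the zinc regulon 3 of 15, ZPS1 (1.75), the regulator ZAP1 (1.37) and FET4 (1.29, adjusted p = 0.143). Of 21 chaperones 6 rose and 1 fell, the risers including SSE2 (1.80), SSA4 (1.73) and the disaggregase HSP104 (1.54, adjusted p = 0.857). In ergosterol synthesis ERG25 (1.80) and ERG1 (1.01, lost in 12 of 41 settings) rose of 23 genes (adjusted p = 0.0507), and in phospholipid synthesis the CTP synthase URA8 (1.21) of 20 (adjusted p = 0.0789). Among 20 cell wall genes 4 rose, with SED1 at 1.44, EXG1 at 1.29 and PST1 at 1.17, and CWP1 fell by 1.35 (adjusted p = 0.385). In the mating response 1 of 18 was called, PRM2 (1.18, n = 4 in the last window, adjusted p = 0.905 for the list), but its 15 to 90 min mean of 3.34 log2 RPM lay under the lowest floor of the last window (3.68), so falling depth alone could give this call. Counts adjusted over the list alone equalled those over all genes for all 28 lists.

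Of the small lists, mating type alpha and meiosis genes had 2 tested members each, and among them SAG1, the alpha-agglutinin, rose (1.76 ± 0.35, n = 4 in each window). Mitochondrially encoded RNAs and the auxotrophy markers had 0 tested members, and HIS3, LEU2 and MET17 had no value in any sample.

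In total, limma called 771 of the 4742 genes between these windows, 610 up and 161 down, and every tested gene with an absolute log2 difference of at least 1 also passed the adjusted p, so the fold threshold sets the count. After centring each sample on its median 464 were called, 236 up and 228 down, and with a lag-1 correlation 437. With missing values filled at 10 reads 1154 were called, 995 up and 159 down. For 56 of the 610 rises the 15 to 90 min mean lay under the floor of every later library with a value, so any value found there was higher; among named genes with missing late values these were DAL80, SDH2, FET4, ZPS1, SAG1 and PRM2. In all 91 named genes called here, each of the 285 to 360 min samples with a value lay on the called side of the 15 to 90 min mean. These genes were chosen from the calls of this comparison, so this describes the calls and adds no separate support. In the 5 libraries at 75, 120, 255, 345 and 360 min, ADA2, a subunit of the SAGA coactivator, lay at 7.83, 8.92, 8.01, 8.33 and 8.45 log2 RPM, against 10.46 or more in the others. The relative median of the ribosomal proteins against 0 min was lower in 3 of them, at −4.31 (255 min), −3.94 (345 min) and −3.85 (360 min), than in neighbours at −2.99 (240 min), −2.43 (270 min) and −2.39 (330 min). Without these 5 libraries 613 genes were called, 135 ribosomal proteins fell (relative −2.20), and 12 PHO genes, 35 stress genes, 16 nitrogen genes, 15 respiratory genes, 11 autophagy genes and 8 M/G1 genes rose.

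**Figure D2:**
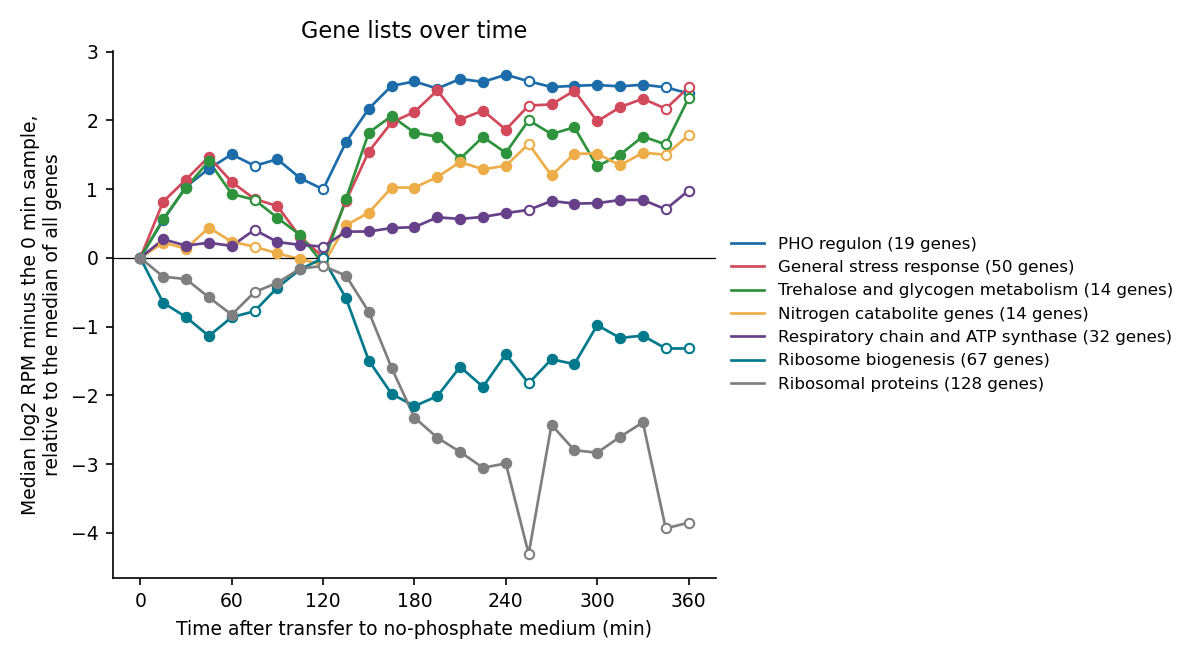
Medians of 7 gene lists over the time course, as log2 RPM minus the 0 min sample and minus the median of all genes (vertical axis), against minutes after the move to no-phosphate medium (horizontal axis), over genes with a value in all 25 samples. Lines show the PHO regulon, general stress response, trehalose and glycogen, nitrogen catabolite, respiratory, ribosome biogenesis and ribosomal protein genes, and open points mark the 5 libraries of low ADA2. Ribosomal proteins end lowest, at −3.85 at 360 min.

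**Figure D3:**
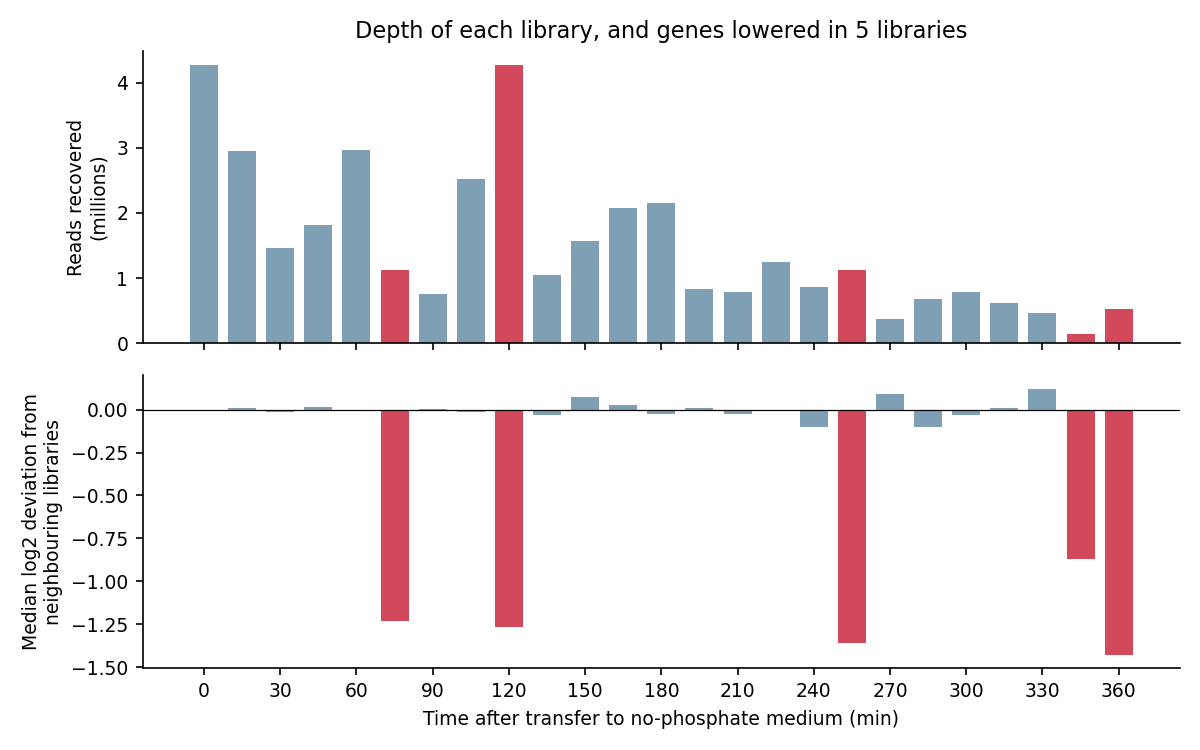
Recovered reads per library in M (bars of the upper panel) and the median log2 deviation from neighbouring libraries of the genes lowered in the 5 libraries of low ADA2 (bars of the lower panel), against minutes after the move to no-phosphate medium. These genes were chosen as lower in the 5 libraries than in the others, so the lower panel restates that choice. The 5 libraries, in red, deviate by −1.23, −1.27, −1.36, −0.87 and −1.43, while the shallow libraries at 270 and 330 min lie at 0.09 and 0.12.

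Set against the single high-phosphate library, the last window shows the whole distance covered. All 19 tested PHO genes rose (relative median 2.43, limma's camera test, adjusted p = 1.24e-22), and the list call held with an estimated correlation (adjusted p = 0.0315). PHO5 rose 20.1-fold (4.33 ± 0.59 SE, limma adjusted p = 2.75e-05), PHM8 by 3.97 ± 0.73, PHM6 by 3.94 ± 0.59, PHO89 by 3.74 ± 0.60, SPL2 by 3.48 ± 0.45 and PHO84 by 3.46 ± 0.30 (limma adjusted p = 5.05e-08). The smallest rises were those of VTC4 (1.84 ± 0.62, limma adjusted p = 0.0272), VTC2 (1.84 ± 0.25), PHO86 (1.40 ± 0.25) and PPN1 (1.38 ± 0.28). After centring, VTC4, PHO86 and PPN1 lost their calls.

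The 10 largest rises in this comparison among genes with a standard symbol and a value in all 25 samples were GRE1 (36.6-fold, 5.19 ± 0.74), HSP26 (5.03), FMP16 (4.86), SIP18 (4.84), DDR2 (4.46), HPF1 (4.39), MSC1 (4.34), PHO5, GND2 (4.28) and the catalase CTT1 (4.25). Stress genes rose in 51 of 56 cases (53 adjusted over the list alone, relative median 2.21, limma's camera test, adjusted p = 3.11e-17), and trehalose and glycogen genes in 16 of 17 (relative median 1.71, adjusted p = 0.000350). Nitrogen genes rose in 19 of 23 (relative median 1.19, adjusted p = 6.78e-06), autophagy genes in 14 of 18 (1.33, adjusted p = 0.000122), TCA genes in 19 of 25 (0.84, adjusted p = 0.000361), respiratory genes in 28 of 36 (29 adjusted over the list alone, 0.82, adjusted p = 3.29e-12) and glycolysis genes in 8 of 21 (0.45, adjusted p = 0.000377), all by limma's camera test. With an estimated correlation all 7 were lost, with adjusted p = 0.352 (stress), 0.481 (trehalose), 0.352 (nitrogen), 0.352 (autophagy), 0.396 (TCA), 0.227 (respiratory) and 0.481 (glycolysis).

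Ribosomal proteins fell in 134 of 137 cases (135 adjusted over the list alone, relative median −3.10, limma's camera test, adjusted p = 1.21e-100), and the call held with an estimated correlation (adjusted p = 0.0315). Among genes with a value in all 25 samples the 10 largest falls were RPL31A (−3.29 ± 0.95, limma adjusted p = 0.0107), FCP1 (−3.18), RPS26B (−3.13), RPL9A (−3.12), RPS22A (−3.11), RPP2A (−2.99), RPS19A (−2.99), RPS27B (−2.99), RPS1B (−2.96) and RPL27A (−2.94). Ribosome biogenesis genes fell in 4 of 85 cases (0 adjusted over the list alone), RRP5 (−1.47), NOP1 (−1.39), UTP22 (−1.39) and UTP10 (−1.26), and 3 RNA polymerase I subunits fell, RPA135 (−1.69), RPA190 (−1.66) and RPA12 (−1.55). Both of these lists stood lower (relative medians −1.26 and −1.10, limma's camera test, adjusted p = 1.38e-18 and 3.69e-07), and with an estimated correlation both had adjusted p = 0.352.

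Among the other lists, G2/M genes (5 of 16 up, limma's camera test, adjusted p = 0.0296) and phospholipid genes (1 up and 1 down of 20, relative median −0.50, adjusted p = 0.0247) passed, and both were lost with an estimated correlation (adjusted p = 0.399 and 0.396). Single calls included HXT5 (5.13 ± 0.63), HSP42, a small heat shock protein (3.23 ± 0.80), the citrate synthases CIT2 (2.51) and CIT1 (2.17), and SAM1, which fell by 2.04 ± 0.40.

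In limma, 1144 genes passed in this comparison, 952 up and 192 down, which became 394 and 352 after centring, 624 in total under quantile normalization and 671 with a lag-1 correlation. Of the rises, 254 had missing late values. For 154 rises the 0 min value lay under the floor of every late library with a value, so any value found there was higher. Among them DAL80 (nitrogen), RIP1 (respiratory) and SDH2 (TCA), counted in the lists above, each had 5 late values. The fall of RPL31A, RPS27B and the biogenesis and polymerase I genes was not called with a lag-1 correlation, and every value depends on the single 0 min library.

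Comparing adjacent windows brackets the change, and the medians of the lists place much of it before 195 min: ribosomal proteins had a relative median of −0.12 at 120 min, −2.32 at 180 min and −2.62 at 195 min, and stress genes 0.02, 2.12 and 2.44. From 105 to 180 min to 195 to 270 min, ribosomal proteins fell in 135 of 137 cases (relative median −2.18, limma's camera test, adjusted p = 3.70e-167, and with an estimated correlation adjusted p = 0.00104), among them RPL21A (−2.40 ± 0.55), RPL9A (−2.31 ± 0.40), RPS22A (−2.21) and RPL24A (−2.18). All 4 were low in the 255 min library of low ADA2, RPL21A most so, at 3.74 log2 RPM against 7.14 or more in the rest of that window. Stress genes rose in 37 of 56 cases (relative median 0.87, limma's camera test, adjusted p = 4.83e-10), with GRE1 at 2.73 ± 0.39, GND2 at 2.59, SIP18 at 2.57 and HSP26 at 2.55. PHO genes rose in 8 of 19 (relative 0.53, adjusted p = 0.000331) and nitrogen genes in 10 of 23 (0.67, adjusted p = 1.56e-05), with GAP1 at 2.21 ± 0.36. With an estimated correlation limma's camera gave adjusted p = 0.534 for stress and nitrogen genes and 0.545 for PHO genes.

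In limma 394 genes were called between these windows, 241 up and 153 down, or 99 and 181 after centring each sample. This step is the least secure of those with calls: 0 genes passed with a lag-1 correlation or with every second sample from 30 to 360 min, 127 without the 105, 120 and 135 min libraries, and 262 without the 5 libraries of low ADA2, against 2179 genes at an unadjusted p under 0.05.

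From 15 to 90 min to 105 to 180 min limma called 0 genes, with 234 at an unadjusted p under 0.05 and 0 with voom weights. ADH6, an alcohol dehydrogenase, was the 1 gene past the adjusted p alone (−0.85 ± 0.15, limma adjusted p = 0.0179), named after its value was seen. Without the 105, 120 and 135 min libraries 227 genes were called, 131 up and 96 down. PHO genes stood higher (relative median 0.50, limma's camera test, adjusted p = 8.27e-12) and ribosomal proteins lower (−0.38, adjusted p = 1.64e-22), and with an estimated correlation both were lost (adjusted p = 0.249 and 0.464).

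From 195 to 270 min to 285 to 360 min limma again called 0 genes, with 610 at an unadjusted p under 0.05, 0 with voom weights and 3 under quantile normalization. As lists, G1/S genes stood lower (median −0.33, relative −0.39, limma's camera test, adjusted p = 1.64e-10) and hexose transporters higher (median 0.32, relative 0.26, adjusted p = 0.00460), and the G1/S call held with an estimated correlation (adjusted p = 0.0161). For hexose transporters that correlation was estimated at 0, under the preset 0.01, so the second limma test (adjusted p = 0.0161) was no stricter than the first. HXT4 and RGT2 had 4 values in the last window and HXT7 had 5. The floors there were 3.68 to 6.09 log2 RPM, against 3.01 to 4.73 in the window before. Falling depth could therefore add to this list's rise, which was not tested. Histones (relative −0.45, adjusted p = 1.98e-08), sulfur genes (−0.36, adjusted p = 1.06e-05), proteasome genes (−0.23, adjusted p = 2.05e-07) and biogenesis genes (0.39, adjusted p = 1.10e-10) passed limma's camera test. With an estimated correlation these 4 had adjusted p = 0.0828, 0.144, 0.636 and 0.788.

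Along the 24 no-phosphate samples, limma's spline test found 1866 genes that varied, 1518 with a net rise and 348 with a net fall, or 703 and 631 after centring. They included 16 of 19 PHO genes, 135 of 137 ribosomal proteins, 54 of 56 stress genes, 16 of 17 trehalose and glycogen genes, 20 of 23 nitrogen genes, 16 of 18 autophagy genes and 29 of 36 respiratory genes. Of the ribosome biogenesis genes 68 of 85 varied, although 1 had been called between the first and last windows, whereas 1 of 32 proteasome genes and 3 of 18 mating genes did.

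PHO genes differed in the time of induction, as the plot of PHO genes over time shows, and the times depend on the threshold. At 30 min, the earliest time this measure can give, 7 genes had reached 0.5 of their highest log2 rise above 0 min: PHO12, PHO81, PHO84, PHO86, SPL2, VTC1 and VTC3. HOR2, PHO11, PHO8 and VTC2 followed at 45 min. The other 8 reached this level later, with PHM6 at 135 min, GDE1, KCS1, PHM8, PHO5, PHO89 and PPN1 at 150 min and VTC4 at 165 min. This difference was not seen with 0.25 of the highest value as the threshold, where these 8 had times of 30 to 60 min. At 1 log2 above 0 min, PHM6 and PHM8 were at 30 min and PHO5 and PHO89 at 45 min, so part of their increase came early. The median over the 19 genes was 45 min. It moved to 165 min with 0.75 of the highest value as the threshold. With the lowest running median as the zero level it was 150 min over 16 genes, PHO86, VTC2 and VTC3 having no time, and SPL2 was at 120 min, VTC1 at 135, PHO12 at 150, PHO84 at 165 and PHO81 at 195 min, so the difference was not seen there either. With no replicate course the error of these times is unknown, and the interval of 15 min is only their resolution. Of 111 alternative times 77 stayed within 15 min and 34 moved further. PHO8 moved from 45 to 135 min with a running median of 5, and VTC4 from 165 to 345 min with no running median.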

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

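Of the tests in this part, those of library depth and of VTC4 at 345 min were chosen after the result was seen, the 5 libraries were picked from the data, and the tests of the median run of A and of gene overlap were fixed before theirs. The tests of the mean run of A, also at matched length, were not among those fixed beforehand. Among the 320 windows of named genes, 31 (9.69%) held 1 sample far from the other samples of its window by Dixon's criterion, where chance gives about 1 in 20. In log2 RPM, the values at 15 min were 6.80 for DDP1, 9.40 for PHO12 and 2.90 for PRM2, each the lowest of its window. At 75 min GLN1 (7.48), RPL31A (10.11), RPL8A (8.90), SDH4 (4.83) and SER3 (3.73) were low. ERG25 at 195 min (10.32) and ADE17 at 270 min (8.72) were low as well. At 255 min RPL21A (3.74), RPL24A (7.05), RPL9A (5.79) and RPS22A (6.77) were low, and HXT5 (6.78) and SIP18 (8.92) high. At 345 min LYS20 (9.12), MET30 (6.86), MET5 (7.41), MFA1 (11.19) and VTC4 (10.36) were high, and VTC3 (10.66) was low. At 360 min COX5B (9.12), GPG1 (9.44), HSP26 (12.66), INH1 (8.92), KCS1 (8.63), RIP1 (6.43) and STF1 (9.53) were high, and RPL8A (4.90) and RPS27B (5.98) were low.

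Of these 31, 26 lay in the libraries at 75, 120, 255, 345 and 360 min, in which a limma term for the 5 libraries lowered 128 of 4730 genes and raised 4 (CRM1, FAL1, JEN1 and RIP1); the lowered genes included THG1 (−2.83), IMP1 (−2.77), RPS20 (−2.76), EDC1 (−2.71), ADA2 (−2.64), RNH70 (−2.31) and 16 of 137 ribosomal proteins. Shallow depth as the whole cause is argued against by the depths of the 5 libraries. The 120 min library, at 4.263 M reads, was the deepest without phosphate, and the median deviation of the lowered genes there was −1.27. Those at 75 and 255 min (1.128 and 1.120 M) lay near the median depth of 1.12 M. In the shallow libraries at 270 and 330 min the median deviation of the lowered genes from neighbouring libraries was 0.106 on average. That value could not decide, because the genes were chosen as lower in the 5 libraries than in the others. Gene overlap is argued against by 117 of the 123 lowered genes with a position, which overlap no other gene. The shares that overlap differed by 3.13 percentage points (4.88 against 1.75%, two-sided Fisher's exact test, p = 0.0244). Priming or slippage at runs of A may still play a part: the median longest run in coding sequence differed by 0 (6 against 6 bases, two-sided permutation test, p = 1), and the mean differed by 0.13 (p = 0.356), or by 0.26 at matched length (p = 0.0491). The bound of 0 set beforehand could not decide this, because whole-number runs tie at 6 and coding models hold no 3′ UTR. Nothing in the labels gives a library batch, and no biological explanation was tested.

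VTC4 reached 10.36 log2 RPM at 345 min, from 192 reads, against 7.82 ± 0.24 (SD, n = 5) in the rest of its window, and had the highest deviation from the neighbouring library (2.31) of the 539 genes with 50 reads or more there, followed by PEX2 (1.90), LYS20 (1.77) and PRX1 (1.71). Counting error is argued against by the 95% Poisson interval, which runs from 10.14 to 10.56, above the highest other value of 8.06. A shared cause with the other 4 libraries of low ADA2 is argued against by their median deviation of −0.64 for VTC4. RNA of cells without the DAmP allele could raise VTC4, but VTC4 was not the only high gene there, as PEX2, LYS20 and PRX1 show. VTC4 minus VTC3 was −0.30 at 345 min against −3.27 to −2.71 in the other 5 samples and −1.48 at 0 min. This explanation stays open, because all samples carry 1 genotype and a library without the allele was not analysed here.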

How the results depend on the processing

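Of the settings in this part, voom weights, filling at 10 reads, and leaving out or fitting a term for chosen sets of libraries were added after the data were seen. The cause of the moves below was not tested. For 285 to 360 against 15 to 90 min, centring gave 464 genes (236 up, 228 down, against 610 and 161), quantile normalization 486 (242, 244), a lag-1 correlation 437 (294, 143) and no fold threshold 2336. For 15 to 90 min against 0 min, quantile normalization gave 4, every second sample from 15 to 345 min 2, a lag-1 correlation 3 and voom weights 12. For 285 to 360 min against 0 min these were 746 (394 up, 352 down, against 952 and 192) for centring, 624 (327, 297) for quantile and 671 for lag-1. Windows of other sizes changed the times compared as well: with 3 samples, 330 to 360 min against 0 min gave 343 genes and 15 to 45 min against 0 min 3, and with 8 samples 135 to 240 against 15 to 120 min gave 417. For 105 to 180 against 15 to 90 min no fold threshold gave 1, and leaving out the 105, 120 and 135 min libraries gave 227 (and 49 for 15 to 90 min against 0 min and 9 for 285 to 360 against 195 to 270 min). For 195 to 270 against 105 to 180 min every second sample from 30 to 360 min and a lag-1 correlation both gave 0, no fold threshold 1598, leaving out the 5 libraries of low ADA2 262, and leaving out 105, 120 and 135 min 127, while 241 up and 153 down became 99 and 181 by centring and 125 and 170 by quantile normalization. For 285 to 360 against 195 to 270 min quantile normalization gave 3, at least 1 value per window 1, and leaving out the 5 libraries 1. The spline gave 1204 genes over complete genes, 1181 with voom weights on these, and 3066 without a fold threshold, and 1518 with a net rise and 348 with a net fall became 703 and 631 by centring and 553 and 893 by quantile normalization. The median time of induction moved from 45 to 165 min (0.75 of the highest value) and to 150 min over 16 genes (lowest running median as zero). PHO86 reversed for 285 to 360 against 15 to 90 min after centring (−0.12, limma adjusted p = 0.425). Centring subtracts from each sample its median over genes with a value in all 25 samples. Leaving out each no-phosphate sample in turn gave 693 to 801, 5 to 9 and 1038 to 1181 genes for the 3 comparisons first named, 0 to 1, 298 to 532 and 0 to 1 for adjacent windows, 1701 to 1918 for the spline and 12 to 16 gene lists. Of 9123 comparisons of named genes 8765 kept direction and side of the threshold, 333 lost a call, most often with a lag-1 correlation (60), centring (53) or quantile normalization (52), 24 gained one and 1 reversed. Of 1668 for lists 1551 kept both and 117 lost a call, and of 111 induction times 77 stayed within an interval and 34 moved. The lag-1 correlation was 0.517 for windows and 0.331 for the spline. Depth limits genes near 10 reads, since the floor in RPM is higher in shallow libraries. No paired analysis was possible because numbers within windows follow time order only. Alternatives for counts (DESeq2, edgeR) and for a pseudocount did not apply to log2 values.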

Other observations

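Of the tests in this part, all those of the stress genes and of other splits of the samples were chosen after the result was seen. Within the first windows, the median level of stress genes went up, returned and went up again. These are medians of single libraries, and the return was not tested gene by gene. From 15 to 90 min 0 of 56 stress genes were called against 0 min. The list call was lost with an estimated correlation (limma's camera test, adjusted p = 0.512). For the 39 stress genes with all values that rose from the first to the last window, the median above 0 min was 1.63 on the log2 scale at 45 min and 1.34 at 60 min, 0.33 at 105 min and 0.15 at 120 min, and then 0.94 at 135 min, 1.79 at 150 min and 3.04 at 195 min. Ribosome biogenesis genes mirrored this, with a relative median of −1.14 at 45 min, 0.00 at 120 min and −2.16 at 180 min. PHO genes returned in part, with relative medians of 1.51 at 60 min, 1.00 at 120 min and 2.57 at 180 min.

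Of 13 genes for phosphate signalling and low-affinity transport, 3 rose between 0 min and 285 to 360 min: the polyphosphate and inositol pyrophosphate phosphatase DDP1 (2.42 ± 0.40 SE, limma adjusted p = 0.000198), the inositol pyrophosphate kinase VIP1 (1.39 ± 0.32, limma adjusted p = 0.00263) and the kinase PHO85 (1.14 ± 0.37, limma adjusted p = 0.0228). After centring each sample, DDP1 alone kept its call (1.91, limma adjusted p = 0.000766). The list did not pass (limma's camera test, adjusted p = 0.761). Of 7 hexose transporters 4 rose, among them HXT7 (2.41) and HXT4 (2.08), which lost their calls after centring (limma adjusted p = 0.0823 and 0.0792) and whose 0 min values lay under the floor of every late library, and this list did not pass in this comparison either (limma's camera test, adjusted p = 0.180).

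A swap or mix of the 105 to 135 min samples with the 0 min sample is argued against by PHO84, SPL2 and VTC3, which held a mean of 1.01 times their rise at 45 and 60 min (1.03, 1.07 and 0.918) while stress genes held 0.317. The libraries of low ADA2 do not account for it, since 105 and 135 min, which are not among them, lay at −0.935 against 60 and 150 min, and nor does depth, since the deep libraries at 45 and 60 min lay 1.01 above 105 to 135 min. A candidate explanation is that washing and transfer set off a first response, and that lack of phosphate set off the second one, which shares genes with it: across 2664 genes outside 6 lists the change from 0 min to 45 and 60 min and that from 105 and 135 to 180 and 195 min correlated at r = 0.799 (Spearman 0.765, genes not being independent replicates). The change from 195 and 210 to 225 and 240 min, taken for contrast, gave r = −0.237 with the first change. The median level of all genes moved little there (0.390 above 0 min at 195 min, 0.444 at 240 min). This contrast therefore cannot show that the match of the rises is specific. Nor can the correlation tell separate triggers from a recurring one. A culture washed and returned to phosphate was not used here, so the candidate was not tested directly.

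Other splits of the samples of each pair of windows, 100 drawn of 462, tested whether any grouping would do. For 285 to 360 against 15 to 90 min only the real split, 1 of the 100, gave 771 genes, and the highest other gave 315. The test treats the samples as exchangeable, which samples in time order are not. For 195 to 270 against 105 to 180 min also 1 split, the real one, gave 374 genes in a fit of these windows alone, and the highest other gave 319. The splits do not allow for the lag-1 correlation of 0.517 between consecutive samples, with which 437 calls were left in the first and 0 in the second of these comparisons. The splits alone therefore exclude chance for neither comparison. For 105 to 180 against 15 to 90 min the real split gave 0 genes and the highest other 4, and for 285 to 360 against 195 to 270 min these were 0 and 1, so all 100 splits had to give as many, and nothing follows about chance. For the count of gene lists in the first of these comparisons 25 of 100 splits gave at least the 12 lists of the real split in a fit of both windows alone, with a highest other of 17, so chance cannot be excluded for that count.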
